A study of Homo sapiens with 12 samples.

How the data were processed

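Total RNA from 3 human lung cancer cell lines was hybridised as biotinylated cRNA to Affymetrix PrimeView expression arrays, which read each gene with 1 or more sets of short probes. Each line was transduced with a lentivirus carrying a short hairpin RNA against MARK2 or with the empty pLKO vector, and each of the 6 groups has 2 arrays. Per the labels, the 2 arrays of a group are biological replicates, so p-values measure the spread between such cultures. The sequence and number of hairpins were not given in the sources used here.

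The deposited values are log2 signals per probe set, made with RMA in Affymetrix Expression Console, per the submitters' processing notes; the software versions were not given in the sources used here. RMA subtracts background, normalises the arrays to one distribution and summarises the probes of a set, so a difference of 1 between the authors' log2 values is a 2-fold difference in signal. The deposited table holds 49395 probe sets on 12 arrays, and array medians run from 7.13 to 7.32. The number of arrays limits the precision, and signal near the background compresses differences, so fold changes of dim genes are understated.

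Probe sets were named through the platform annotation, with gene symbols checked through gene IDs against the RefSeq table of assembly GRCh38.p14. Of the probe sets, 44994 have 1 gene symbol, 1832 have several and 2569 have none there. Those with several or none and the 102 control probe sets were left out of gene tests, and 44988 remained. Of these, 44961 matched a gene ID in the table. They represent 18132 genes, and 11734 of these have several probe sets. Each gene was represented by its probe set with the highest mean over the 12 arrays. Genes were tested where at least 2 arrays reached a log2 signal of 5, which left 16205 genes; between 15173 and 15870 genes reached that signal in a single array.

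One linear model with a mean for each of the 6 groups was fitted to all 12 arrays with limma 3.58.1 in R 4.3.3, with moderated variances from eBayes, 6 residual degrees of freedom and a prior of 3.52. The contrasts were knockdown minus control in each line, the mean of these 3 changes, and the F test of whether they differ between lines. All tests were two-sided, with Benjamini-Hochberg adjustment over the genes tested and a threshold of 0.05. Standard errors (SE) come from this fit. No 2 arrays of a group were duplicates: replicate arrays had identical values in 0.0526% to 0.0992% of probe sets, and their lowest correlation across all probe sets was 0.995.

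A set of 38 gene lists was fixed before the data were examined and tested in each contrast with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the lists. Camera with a correlation estimated from the arrays, and fry, which asks whether a list's genes move on balance one way, were run beside it. Members were counted by their adjusted p over all genes and also with p adjusted over the list alone. The correlation of changes between lines was computed across genes, which are not independent replicates, so it has no p.

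The rule for named genes was fixed before the data were examined. It takes the 4 MARK genes. For the mean of the 3 lines it takes the 12 largest rises and the 12 largest falls among genes past the threshold with 1 sign in all 3 lines. For each line it takes the 8 largest rises and the 8 largest falls among genes past the threshold whose knockdown arrays lie on one side of both control arrays. For the differences between lines it takes the 8 genes with the smallest p, and from each list described up to 4 members past the threshold with the largest change, or up to 2 given as values where none passes. Genes on the Y chromosome and XIST were never named. A gene outside the rule is said to be chosen after its values were seen.

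The control probe sets for the 3' and 5' ends of GAPDH and ACTB were read on each array as a measure of RNA integrity, since labelling starts at the 3' end of the transcript. Positions of the gene probe sets along their transcripts were not used here.

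The pipeline was tested on simulated data: 16205 genes with the control means and the fitted spread of the real data, of which 200 were changed by known amounts in all lines. For the mean of the 3 lines, 42% of the genes changed by 0.25, 90% of those changed by 0.5 and 100% of those changed by 1 or 2 (log2) were recovered, and 6.74% of the calls were false. In H1650, H1693 and H1993, 2%, 2% and 4% of those changed by 0.25, 56%, 56% and 50% of those changed by 0.5 and 100% of the larger changes were recovered, and 7.86%, 5.84% and 9.93% of the calls were false. The simulated genes varied independently and each had the same spread in all lines. In the real data the SD of the difference between replicate arrays was 0.191 (control) and 0.222 (knockdown) in H1650. It was 0.140 and 0.144 in H1693 and 0.172 in both groups of H1993. The simulated rates therefore need not hold for the real arrays, least of all in H1650.

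Alternatives covered replicate and array-code terms in the model, the filter on dim genes, the choice of probe set, rescaling of the arrays, the variance model, array weights, fits on 1 line, a fold minimum of 1.5, each array left out in turn and the set test. An additive model of line and treatment was also fitted. Fits with the 3'-5' difference as a covariate, without H1650, over H1693 and H1993 only, and with crossed replicate numbers were added after seeing the data.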

Results

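Gene expression was profiled after knockdown of MARK2 in 3 non-small cell lung cancer lines, H1650, H1693 and H1993, described by the submitters as lines with high MARK2. MARK2 is a serine/threonine kinase that phosphorylates microtubule-associated proteins and acts in cell polarity. In each line 2 arrays of cells with a hairpin against MARK2 were set against 2 arrays of cells with the empty pLKO vector, 12 arrays in all. The series relates MARK2 to the response to DNA damage and to cisplatin, so lists of DNA repair and drug response genes were among those compared. No cisplatin-treated group was analysed here.

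MARK2 signal fell in H1993 and H1693, and its change in H1650 did not pass the threshold. In H1993 it was 9.12 ± 0.08 (log2 signal, SD, n = 2) in the control and 6.77 ± 0.01 in the knockdown arrays, a change of -2.35 (SE 0.16, limma adjusted p = 6.47e-06) that left 19.6% of the control signal. In H1693 it went from 7.86 ± 0.15 to 6.60 ± 0.04, a change of -1.27 (adjusted p = 0.000258) that left 41.6%. In H1650 it was 5.94 ± 0.19 in the control and 5.65 ± 0.38 in the knockdown arrays, and the change of -0.29 (SE 0.16) did not pass the threshold (adjusted p = 0.156). Without knockdown replicate 1 of H1650 that change was -0.56 and passed, without knockdown replicate 2 it was -0.02, and after quantile normalisation of the tested genes it was -0.44 and passed. The change differed between the lines (F test, adjusted p = 0.000182), and H1993 fell by more than H1693, with a difference of -1.08 (adjusted p = 0.00781). The dimmer MARK2 probe set changed by -2.12 in H1993, -0.58 in H1693 and 0.03 in H1650. In the H1650 control arrays the dimmer probe set was at 4.50 and the brighter at 5.94, both near the log2 floor of 5 used for testing. Changes of dim signals are understated, so -0.29 does not measure how far MARK2 was knocked down in H1650. The knockdown arrays of H1693 and H1993 ended at similar levels, 6.60 and 6.77, from controls at 7.86 and 9.12. On the dimmer probe set they ended at 4.58 and 4.76, near its 4.50 in the H1650 control arrays. Background may therefore also limit the fall in H1693, and a weaker knockdown there than in H1993 is not shown. Of the related kinases, MARK1 fell in H1693, by 0.47 (SE 0.13, adjusted p = 0.0206; difference between lines, adjusted p = 0.0333), although its other probe set was at -0.01 there. MARK3 and MARK4 did not pass the threshold in any line, with changes between -0.13 and 0.17.

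**Figure D1:**
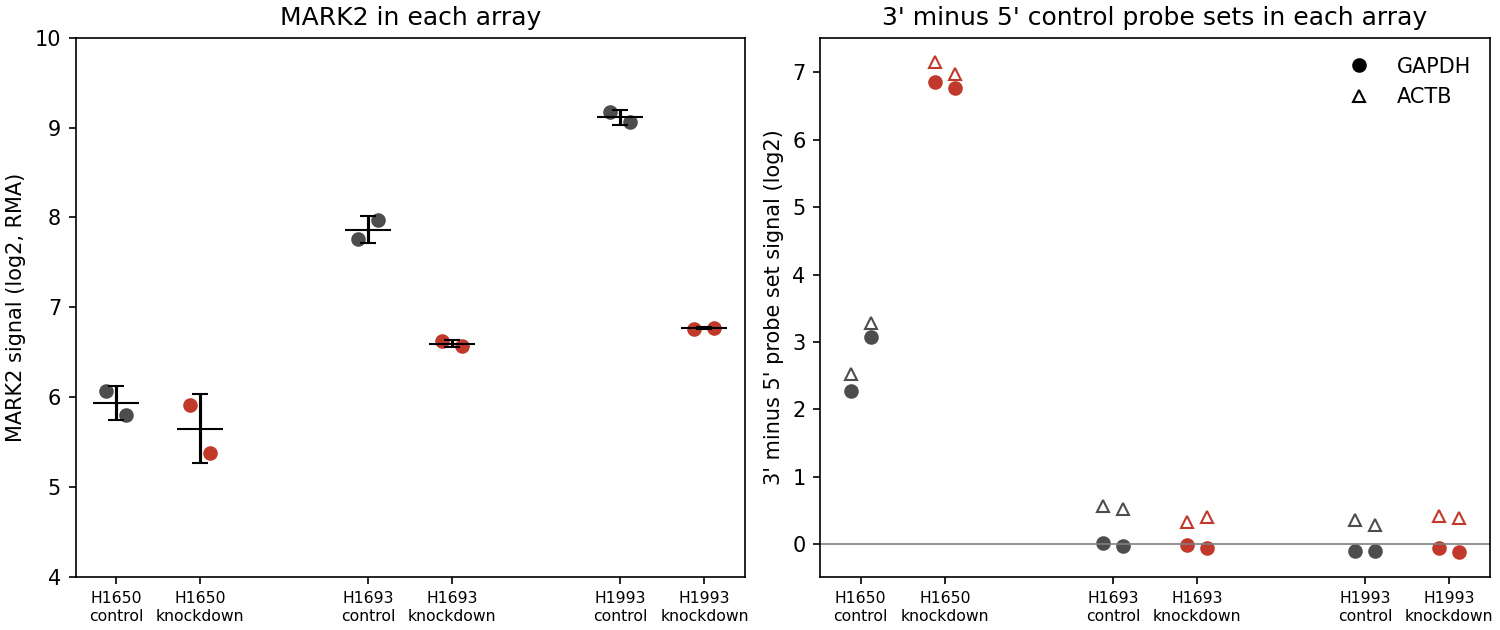
Left, MARK2 signal (log2, RMA) of the 12 arrays by line and treatment; points are arrays, horizontal bars the mean and error bars the SD of 2 arrays; right, signal of the 3' minus the 5' control probe sets of GAPDH (filled circles) and ACTB (open triangles) on the same arrays (log2). The knockdown arrays of H1993 and H1693 lie below their controls on the left, and on the right the H1650 arrays stand apart, with a mean GAPDH difference of 2.68 in the control and 6.82 in the knockdown group.

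The arrays of H1650 differed from the others in RNA integrity, and the difference moved with the knockdown. The 3' minus 5' signal of GAPDH was 2.68 ± 0.56 (log2, SD, n = 2) in H1650 control and 6.82 ± 0.07 in H1650 knockdown arrays, or 6.39-fold and 113-fold. For ACTB the values were 2.90 ± 0.54 and 7.06 ± 0.13. In H1693 the GAPDH difference was 0.00 ± 0.03 in the control and -0.03 ± 0.02 in the knockdown arrays, and in H1993 it was -0.10 ± 0.01 and -0.09 ± 0.05. Probe sets of the same gene also disagreed more in H1650. Among 5929 genes with 3 or more probe sets, the median SD between the changes of a gene's probe sets was 0.39 in H1650, against 0.14 in both H1693 and H1993. The mean of the 3 lines includes these H1650 arrays.

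Over the mean of the 3 lines, SYTL5, a synaptotagmin-like vesicle protein, had the largest rise named by the rule, 2.34 (SE 0.07, adjusted p = 4.74e-08), although its 2 probe sets in H1650 were at -0.01 and 2.93. Next, LAMP3, a lysosomal membrane protein, rose by 2.12 (SE 0.04, adjusted p = 1.35e-08), with its other probe set at 1.13, 1.94 and 0.47 in H1650, H1693 and H1993. The interferon-induced genes IFI44 and IFI44L rose by 1.90 and 1.60, and NLRC5, an activator of MHC class I genes, by 1.81. The p53-inducible TP53INP1 rose by 1.62, the neuronal microtubule-associated protein MAP2 by 1.44 and the lipase LIPH by 1.49. PGM2L1, KLRC3, CA13 and TRANK1, the other leading rises, changed by 1.96, 1.65, 1.63 and 1.44. The probe sets of CA13 in H1650 ran from -0.28 to 2.52 and those of LIPH from -0.14 to 0.92. The other probe set of TP53INP1 was at 0.32, 0.28 and 0.09 in H1650, H1693 and H1993, against 1.98, 1.16 and 1.72 for the probe set used. In H1693 probe sets of MAP2, NLRC5 and PGM2L1 were as low as -0.20, -0.04 and 0.02 and those of IFI44L ran from -0.11 to 0.60, and in H1993 those of IFI44 and NLRC5 as low as -0.10 and 0.27. The actin-bundling protein FSCN1 had the largest fall named by the rule, -2.10 (SE 0.09, adjusted p = 2.15e-07), followed by the insulin-like growth factor binding protein IGFBP6 at -1.71. CDC25B, a phosphatase that activates mitotic CDK1, fell by 1.59, UBE2S, an E2 enzyme of the anaphase-promoting complex, by 1.56, and MYBL2, a transcription factor of the cell cycle, by 1.28. The DNA strand-break sensor PARP1 fell by 1.44 and TAF10, a subunit of TFIID, by 1.42. IGFBP2, PLRG1, MARCHF4, GET3 and MARK2 changed by -1.40, -1.37, -1.34, -1.31 and -1.30. Most of these means were unequal over the lines, and several falls were carried by H1650, the line with the 3' minus 5' difference. In H1650, H1693 and H1993, CDC25B was at -3.13, -0.80 and -0.83, UBE2S at -3.52, -0.63 and -0.54 (not passed in H1993, adjusted p = 0.0569) and MYBL2 at -2.45, -0.68 and -0.71. IGFBP2 was at -3.09, -1.02 and -0.10 (not passed in H1993, adjusted p = 0.614), PLRG1 at -3.50, -0.17 and -0.42 (not passed in H1693, adjusted p = 0.374) and GET3 at -2.52, -0.55 and -0.87. MARCHF4, at -1.06, -2.56 and -0.42, was lowest in H1693. Among the rises, IFI44L was at 3.01, 0.13 and 1.65 and did not pass in H1693 (adjusted p = 0.296), and SYTL5 in H1993, PGM2L1 in H1693, CA13 in H1693 and MAP2 in H1693 rose by 0.92, 0.77, 0.60 and 0.42.

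In all, 7885 of 16205 genes passed the threshold over the 3 lines, 4727 higher and 3158 lower, and 1246 of them changed by at least 1.5-fold. After quantile normalisation 4047 were higher and 4057 lower, and the additive model of line and treatment called 3660 genes. With the GAPDH 3' minus 5' difference as a covariate 30 genes passed, with the SE of MARK2 at 0.40 against 0.09 without it, and over H1693 and H1993 alone 6661 did. Several leading falls were larger in H1650: FSCN1 changed by -3.99 there, against -1.53 in H1693 and -0.79 in H1993 (difference between lines, adjusted p = 9.64e-06), and its 3 probe sets in H1650 ran from -3.99 to -0.07. PARP1 changed by -3.20, -0.48 and -0.64 in the 3 lines in that order, with probe sets in H1650 from -3.20 to 0.40 and in H1693 from -0.48 to -0.04 (difference between lines, adjusted p = 7.18e-06). IGFBP6 and TAF10, by contrast, were the 2 genes that fell over 2-fold in each line, by 1.91, 1.43 and 1.78 for IGFBP6 and by 1.33, 1.15 and 1.79 for TAF10 in H1650, H1693 and H1993.

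Cell cycle genes were lower after knockdown. Of 37 measured genes of mitosis and G2/M, 36 fell and none rose over the 3 lines, with a median change of -0.49 (camera adjusted p = 1.66e-20; adjusted p = 0.0542 with an estimated correlation). The mitotic kinases PLK1 and AURKB fell by 1.20 and 1.02, and FOXM1, a transcription factor of mitotic genes, by 1.19. PLK1 was at -2.33, -0.96 and -0.30 in H1650, H1693 and H1993, with another probe set at 0.38 in H1650. The mitosis count was also 36 when adjusted over the list alone. By line, all 37 fell in H1693 (median -0.97, camera adjusted p = 5.01e-26) and 35 fell in H1993 (median -0.54, adjusted p = 3.47e-17; adjusted p = 0.123 with an estimated correlation), and in H1650 13 fell and 8 rose (median -0.03). Of 38 genes of DNA replication and G1/S, 33 fell over the 3 lines (median -0.43, camera adjusted p = 4.71e-17; adjusted p = 0.0542 with an estimated correlation; 33 adjusted over the list alone). The GINS subunit GINS2 fell by 1.06, and the helicase subunits CDC45 and MCM2 each fell by 0.88, with a probe set of CDC45 at 0.09 in H1650. All 38 fell in H1693 (median -0.85, adjusted p = 2.26e-24) and 21 in H1993 (median -0.31, adjusted p = 4.87e-07; adjusted p = 0.187 with an estimated correlation), and in H1650 16 fell and 8 rose (median -0.10). Adjusted over the list alone, the replication counts were 22 lower and 1 higher in H1993 and 16 lower and 9 higher in H1650, and the mitosis counts in H1650 were 13 lower and 9 higher. In H1693 both lists also passed with an estimated correlation (adjusted p = 0.0453 for mitosis and 0.0435 for replication), and of all list calls in the 4 comparisons these were the 2 that did. In H1650, where the mean GAPDH 3' minus 5' difference was 6.82 after knockdown, camera gave adjusted p = 0.023 for mitosis and 0.00746 for replication, and 0.671 and 0.599 as adjusted p with an estimated correlation.

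**Figure D2:**
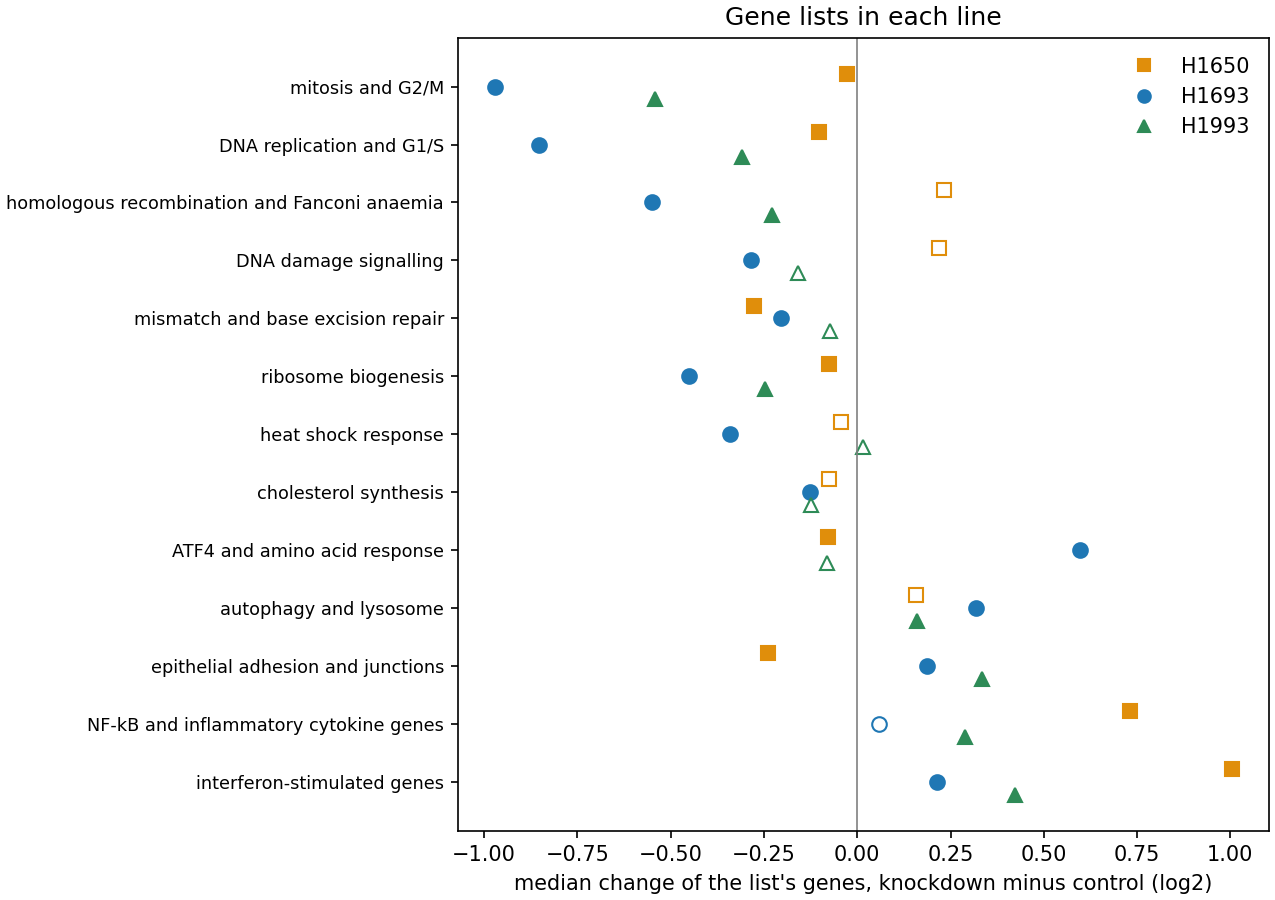
Median change of the measured genes of 13 gene lists in each line, knockdown minus control (log2); squares are H1650, circles H1693 and triangles H1993, filled where the list passed camera at its preset correlation and open where it did not. Mitosis genes lie at -0.97 in H1693 and -0.54 in H1993, and interferon-stimulated genes at 1.00, 0.21 and 0.42 in H1650, H1693 and H1993.

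Genes of homologous recombination fell in H1693 and H1993. Of 28 genes of homologous recombination and the Fanconi anaemia pathway, 20 fell and none rose in H1693 (median -0.55, camera adjusted p = 1.24e-07; adjusted p = 0.0797 with an estimated correlation; 21 fell and 2 rose adjusted over the list alone). In H1993 12 fell and 1 rose (median -0.23, adjusted p = 6.63e-05; adjusted p = 0.2 with an estimated correlation). The helicase BLM fell by 1.12 in H1693 and 0.53 in H1993, and the nuclease subunit EME1 by 1.09 and 1.04. In H1650 the list did not pass, with 14 members higher and 6 lower, and its median of 0.23 and camera's direction, down, had opposite signs (adjusted p = 0.991). Over the 3 lines 19 fell and 5 rose (adjusted p = 7.24e-05; adjusted p = 0.225 with an estimated correlation). Of 24 genes of DNA damage signalling, 15 fell and none rose in H1693 (median -0.29, adjusted p = 1.41e-06; adjusted p = 0.0797 with an estimated correlation), among them the checkpoint genes CLSPN (-1.21) and CHEK1 (-0.85), and MRE11 (-0.86, with probe sets up to 0.18) and TOPBP1 (-0.82). In H1993 10 fell and 4 rose and the list did not pass (adjusted p = 0.0731), and its change differed between H1993 and H1693 (camera adjusted p = 0.0066; adjusted p = 0.369 with an estimated correlation). Of 25 genes of mismatch and base excision repair, 11 fell and 3 rose in H1693 (adjusted p = 0.00215; adjusted p = 0.292 with an estimated correlation), including the glycosylases NEIL2 (-1.17) and UNG (-0.87). In H1993 9 fell and 1 rose (median -0.07) and the list did not pass (adjusted p = 0.0704). In H1650, with its 3' minus 5' difference, 13 fell and 4 rose (adjusted p = 0.00746; adjusted p = 0.599 with an estimated correlation). Over the 3 lines 15 of these genes fell and 5 rose (adjusted p = 0.000679; adjusted p = 0.302 with an estimated correlation), and of the damage signalling genes 13 fell and 6 rose (adjusted p = 0.0289; adjusted p = 0.348 with an estimated correlation). Recombination genes, adjusted over the list alone, had 13 lower and 1 higher in H1993, damage signalling genes 15 lower and 1 higher in H1693 and 11 lower and 4 higher in H1993, and mismatch and base excision genes 12 lower and 3 higher in H1693. Nucleotide excision repair and non-homologous end joining did not pass in any line or in the mean of the 3 lines. End joining had 6 of 10 lower and 1 higher in H1693 (median -0.35, adjusted p = 0.0685) and 5 lower and none higher in H1993 (median -0.22, adjusted p = 0.0646), close to the recombination median of -0.23 in H1993. Over H1693 and H1993 alone, a comparison chosen after seeing the data, end joining passed, with 7 of 10 lower and 1 higher. Its median there was -0.28 (camera adjusted p = 0.032, or 0.32 with an estimated correlation). Nucleotide excision repair did not pass there (camera adjusted p = 0.459). The repair lists were not tested against each other.

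Interferon-stimulated genes were higher in all 3 lines. Over their mean, 32 of 38 rose and 1 fell (median 0.65, camera adjusted p = 8.67e-10; adjusted p = 0.0542 with an estimated correlation; the same counts adjusted over the list alone). In H1650, where RNA integrity differed as above, 32 rose and 1 fell (median 1.00, adjusted p = 4.34e-07; adjusted p = 0.12 with an estimated correlation), in H1693 17 rose and 2 fell (median 0.21, adjusted p = 0.000301; adjusted p = 0.0797 with an estimated correlation), and in H1993 23 rose and 1 fell (median 0.42, adjusted p = 7.28e-07; adjusted p = 0.123 with an estimated correlation). IFI44 rose by 1.63, 2.20 and 1.88 in the 3 lines, with no difference between lines past the threshold (adjusted p = 0.155). The chemokine CXCL10 rose by 2.94 in H1650 and changed by -0.06 and 0.08 in H1693 and H1993. The antiviral genes OAS1 in H1693 and MX1 in H1993 rose by 1.53 and 1.48, with a probe set of OAS1 at 0.08. BST2, the member that fell in H1650, changed by -2.48, with probe sets up to -0.19. NF-kB and inflammatory cytokine genes rose in H1650 (15 of 23, none lower, adjusted p = 0.00446; adjusted p = 0.388 with an estimated correlation), led by CXCL8 at 2.27, with a probe set at -0.08, and TNFAIP3 at 1.96. They also rose in H1993 (12 of 23, 1 lower, adjusted p = 0.00505; adjusted p = 0.187 with an estimated correlation), where the cytokines IL1A and IL1B rose by 2.06 and 1.26. In H1693 3 rose and 1 fell and the list did not pass (adjusted p = 0.443), a difference from H1650 (camera adjusted p = 0.00732; adjusted p = 0.248 with an estimated correlation). Over the 3 lines 17 rose and none fell (adjusted p = 0.0002; adjusted p = 0.119 with an estimated correlation). Adjusted over the list alone, the interferon counts were 33, 18 and 24 higher in H1650, H1693 and H1993 with the falls as above, and the NF-kB count in H1650 was 16 higher and 1 lower.

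Ribosome biogenesis genes were lower, and genes of autophagy and lysosomes were higher in H1693 and H1993. Of 33 ribosome biogenesis genes, 27 fell and none rose over the 3 lines (median -0.30, adjusted p = 9.74e-10; adjusted p = 0.164 with an estimated correlation), 24 in H1693 (adjusted p = 4.71e-10; adjusted p = 0.0853 with an estimated correlation) and 17 in H1993 (adjusted p = 1.98e-06; adjusted p = 0.203 with an estimated correlation), with NOP16 at -1.13 and UTP20 at -1.09 over the 3 lines. In H1650, H1693 and H1993 NOP16 was at -2.09, -0.58 and -0.73 and UTP20 at -2.14, -0.60 and -0.53, and NOP16 had probe sets up to 0.42 in H1650 and 0.06 in H1993. In H1650 14 fell and 9 rose (adjusted p = 0.00804; adjusted p = 0.671 with an estimated correlation) beside the 3' minus 5' difference. Of 29 genes of autophagy and lysosomes, 18 rose and none fell in H1693 (adjusted p = 5.66e-07; adjusted p = 0.0797 with an estimated correlation) and 10 rose and 2 fell in H1993 (adjusted p = 0.0103; adjusted p = 0.271 with an estimated correlation). The autophagy kinase ULK1 rose by 0.67 and 1.11 in these lines, and the sialidase NEU1 by 0.57 and 0.80. In H1650 14 rose and 6 fell and the list did not pass (adjusted p = 0.996), with a median of 0.16 and camera's direction down. Over the 3 lines 15 rose and 1 fell (adjusted p = 0.00762; adjusted p = 0.289 with an estimated correlation). Ribosome biogenesis genes adjusted over the list alone had 28 that fell in H1693 and 19 in H1993, and 20 lysosome genes rose in H1693, 11 rose and 2 fell in H1993, and 16 rose and 2 fell over the 3 lines.

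Other lists passed over the 3 lines as well. Cholesterol synthesis fell (12 of 19, 4 higher, adjusted p = 0.00663; adjusted p = 0.2 with an estimated correlation), with ACAT2 at -0.59 and IDI1 at -0.53. Fatty acid and triglyceride synthesis had 10 of 20 lower and 3 higher (adjusted p = 0.0443; adjusted p = 0.289 with an estimated correlation), a call lost when arrays were centred on their medians (adjusted p = 0.065). Its members DGAT1 and SREBF1, at -0.48 and -0.42, were lower in H1650 and of the opposite sign in the mean of H1693 and H1993. The heat shock response had 12 of 18 lower and 2 higher (adjusted p = 0.00795; adjusted p = 0.302 with an estimated correlation), with the chaperones DNAJB1 and HSPD1 at -0.42 and -0.41. DNAJB1 was at -1.11, -0.31 and 0.16 in H1650, H1693 and H1993 and HSPD1 at -0.70, -0.37 and -0.17, neither past the threshold in H1993, and both had probe sets above 0 in H1650, as HSPD1 had in H1693 (0.50). By line the heat shock list passed in H1693, not in H1650 (adjusted p = 0.191) or H1993 (3 higher, 2 lower, adjusted p = 0.944), and H1993 differed from H1693 (camera adjusted p = 0.000658; adjusted p = 0.276 with an estimated correlation). TGF-beta target genes had 11 of 19 higher and 4 lower (adjusted p = 0.0461; adjusted p = 0.302 with an estimated correlation), including BAMBI at 0.81 (0.19 and not passed in H1693) and SMAD7 at 0.72. In H1650 and H1993 the cholesterol list (adjusted p = 0.169 and 0.0731) and the TGF-beta list (0.68 and 0.103) did not pass, and the fatty acid list passed in no single line (0.188, 0.443 and 0.112 in H1650, H1693 and H1993). With the array codes 1 to 6 against 7 to 12 as a block within each line, the calls of fatty acid, TGF-beta and DNA damage signalling genes over the 3 lines were lost (adjusted p = 0.0513 each). Cytosolic ribosomal protein genes had 13 of 41 lower and none higher, with a median of -0.04 (adjusted p = 0.00218; adjusted p = 0.348 with an estimated correlation), a call lost after quantile normalisation (adjusted p = 0.0961). In H1650 the ribosomal protein list had 8 lower and 2 higher (adjusted p = 0.0208; adjusted p = 0.671 with an estimated correlation; 0.326 after quantile normalisation), and in H1993 4 lower (adjusted p = 0.00296; adjusted p = 0.327 with an estimated correlation). Fatty acid genes, adjusted over the list alone, had 10 lower and 4 higher and TGF-beta target genes 12 higher and 4 lower, and the ribosomal protein list in H1650 8 lower.

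In H1650, where the knockdown arrays had the larger 3' minus 5' difference (6.82 against 2.68 for GAPDH), interferon-stimulated genes were among the largest rises. IFI44L rose by 3.01 (SE 0.08, adjusted p = 4.24e-08), followed by CXCL10, SYTL5 (2.93), NLRC5 (2.59), CA13 (2.52), PGM2L1 (2.45), the mitochondrial kinase CMPK2 (2.43) and the non-coding RNA HCP5 (2.31). Other probe sets of SYTL5, CA13 and CMPK2 were as low as -0.01, -0.28 and 0.08, and those of NLRC5, PGM2L1 and HCP5 as low as 0.63, 0.57 and 0.46. The keratin KRT8 changed by -4.47 (SE 0.15, adjusted p = 1.04e-07), but its 8 probe sets ran from -4.47 to 0.42. The falls of PLRG1 (-3.50), the arginine methyltransferase PRMT1 (-3.50) and the splicing factor SRRM2 (-3.36) likewise had other probe sets at up to 0.92, 0.28 and 0.15. CLIC3 (-3.57), B3GNT3 (-3.57, with another probe set at -0.13) and UBE2S (-3.52) complete the 8 largest falls with FSCN1. Epithelial adhesion and junction genes had 14 of 27 lower and 8 higher (adjusted p = 0.00734; adjusted p = 0.388 with an estimated correlation), with the junction protein JUP at -2.13. ATF4 and amino acid response genes had 15 of 32 lower and 5 higher (adjusted p = 0.000415; adjusted p = 0.388 with an estimated correlation), with the transporters SLC1A5 and SLC7A5 at -2.50 and -2.12, and another probe set of SLC7A5 at -0.31. In all 8656 genes passed, 5954 higher and 2702 lower, with 538 rises and 765 falls over 2-fold. The median change of all genes was 0.15 and went to 0.04 after quantile normalisation, which gave 4737 higher and 3468 lower, so values for this line are to be read against that shift. With the GAPDH 3' minus 5' difference as a covariate, limma called 0 genes of H1650, and 1233 had an unadjusted p below 0.05. The covariate nearly follows treatment in this line and took the SE of MARK2 from 0.16 to 1.18, so the loss of calls says little about the genes.

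In H1693, genes of the amino acid response rose while cell cycle genes fell. Of 32 measured ATF4 and amino acid response genes, 25 rose and none fell (median 0.60, adjusted p = 6.55e-12; adjusted p = 0.0566 with an estimated correlation; 27 rose and 2 fell adjusted over the list alone). TRIB3, a pseudokinase induced by stress, rose by 1.58, PCK2 by 1.40, the mTORC1 inhibitor DDIT4 by 1.25 and the cystine transporter SLC7A11 by 1.18, with a probe set at 0.21. Immediate early genes rose (13 of 23, 1 lower, adjusted p = 0.000215; adjusted p = 0.0797 with an estimated correlation), with FOSB at 1.42, FOS at 1.18 and JUN at 1.13, while FOSL1 fell by 1.03. Probe sets of FOSB and FOSL1 were at -0.09 and -0.22. In H1993 3 immediate early genes rose and 7 fell (median -0.09) and the list did not pass (adjusted p = 0.0892), a difference from H1693 (camera adjusted p = 1.09e-05; adjusted p = 0.0756 with an estimated correlation); in H1650 6 rose and 8 fell (adjusted p = 0.262). The heat shock response had 15 of 18 lower and 2 higher (adjusted p = 0.000215; adjusted p = 0.14 with an estimated correlation), with the small heat shock protein HSPB8 at 1.46 and HSPA4L at -1.08. The immediate early count adjusted over the list alone was 14 higher and 1 lower. Apoptosis regulators had 10 of 29 higher and 3 lower (adjusted p = 0.0157; adjusted p = 0.102 with an estimated correlation), including the death receptor TNFRSF10B at 1.13 and BBC3 at 0.98. The largest rises were MS4A15 (3.17, SE 0.14, adjusted p = 1.3e-06), SYTL5 (3.17), EDIL3 (2.81), AMIGO2 (2.71), LAMP3 (2.50), TRIM2 (2.24), IFI44 and THSD7A (2.14). The largest falls were FGFBP1 (-2.76, SE 0.07, adjusted p = 9.73e-08), MARCHF4 (-2.56), GATM (-2.27), the potassium channel KCNMA1 (-2.19), MC5R (-2.14), the Wnt antagonist SFRP5 (-2.03), the neuropeptide GAL (-1.96) and TAGLN (-1.81). Other probe sets of AMIGO2, SYTL5, EDIL3 and IFI44 were as low as 0.08, 0.55, 0.81 and 0.22, and 1 of KCNMA1 was at -0.10. In all 5346 genes passed, 2763 higher and 2583 lower, with 249 rises and 155 falls over 2-fold.

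Further lists passed in H1693. Unfolded protein response genes had 9 of 24 higher and 2 lower (adjusted p = 0.0168; adjusted p = 0.344 with an estimated correlation). MAPK feedback and ETS genes had 10 of 22 higher and 5 lower (adjusted p = 0.0409; adjusted p = 0.344 with an estimated correlation), a call lost after quantile normalisation (adjusted p = 0.054) and with the replicate block (adjusted p = 0.0514). Epithelial adhesion and junction genes had 11 of 27 higher and 1 lower (adjusted p = 0.00661; adjusted p = 0.152 with an estimated correlation), led by the claudins CLDN3 and CLDN4 at 1.36 and 1.08. Extracellular matrix and integrin genes had 13 of 29 higher and 5 lower (adjusted p = 0.0128; adjusted p = 0.292 with an estimated correlation), with tenascin TNC at 1.93 and another of its probe sets at -0.32. TGF-beta target genes had 11 of 19 higher and 3 lower (adjusted p = 0.00392; adjusted p = 0.142 with an estimated correlation), and cholesterol synthesis genes 8 of 19 lower and 3 higher (adjusted p = 0.045; adjusted p = 0.24 with an estimated correlation), a call lost in the fit without H1650 arrays (adjusted p = 0.0588) and with the replicate block or the array codes as a block (adjusted p = 0.0556 and 0.0589). Adjusted over the list alone, the counts of higher and lower genes were 11 and 5 for MAPK, 11 and 2 for epithelial, 14 and 5 for matrix and 13 and 3 for TGF-beta genes. In H1650 and H1993 the unfolded protein response (adjusted p = 0.851 and 0.698) and MAPK genes (0.871 and 0.549) did not pass, and matrix genes and apoptosis regulators did not pass in H1650 (0.991 and 0.896).

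In H1993, the line with the largest MARK2 change, tubulin and microtubule genes were among the largest rises. The tubulin TUBA1A rose by 2.39, the tubulin-binding protein TPPP by 2.55 and MAP2 by 2.42, although neither tubulins (4 of 13 higher, 1 lower, adjusted p = 0.188) nor microtubule-associated proteins (9 of 24 higher, 2 lower, adjusted p = 0.0704) passed as lists. SMIM5 rose by 3.13 (SE 0.26, adjusted p = 2.24e-05), the decoy receptor TNFRSF11B by 2.75, NOL4L by 2.68, PGM2L1 by 2.65 and the iron exporter SLC40A1 by 2.62. The protease inhibitors SPINK6 and SPINK7 changed by -3.03 (SE 0.10, adjusted p = 2.42e-07) and -2.44. The other large falls were LINC00473 (-2.55), the histone gene H2AC16 (-2.37), MARK2, PPP1R3C (-2.12), DLEU2 (-1.80) and TAF10 (-1.79). Probe sets of NOL4L, SMIM5 and MAP2 were as low as -0.03, 0.23 and 0.61, and the falls of LINC00473 and DLEU2 had another probe set at -0.59 and 0.12. Epithelial adhesion and junction genes rose (17 of 27, 1 lower, adjusted p = 5.83e-05; adjusted p = 0.154 with an estimated correlation), with the tight junction protein CGN at 1.90 and the cadherin CDH1 at 0.85. Extracellular matrix and integrin genes had 14 of 29 higher and 3 lower (adjusted p = 0.00859; adjusted p = 0.271 with an estimated correlation), with the collagen COL6A1 at 1.48 and another of its probe sets at 0.21. Oxidative phosphorylation genes had 8 of 33 lower and 1 higher (adjusted p = 0.0142; adjusted p = 0.271 with an estimated correlation), a call lost after quantile normalisation (adjusted p = 0.0828); they did not pass in H1650 or H1693 (0.964 and 0.466). Adjusted over the list alone, 18 epithelial genes were higher and 1 lower, 16 matrix genes higher and 3 lower, and 10 microtubule-associated genes higher and 3 lower. Apoptosis regulators had 12 of 29 higher and 1 lower (adjusted p = 0.0308; adjusted p = 0.187 with an estimated correlation), including the pro-apoptotic BMF at 1.63, with a probe set at -0.20, and BIK at 1.02, a call lost with the replicate block (adjusted p = 0.0517). In all 5418 genes passed, 3064 higher and 2354 lower, with 380 rises and 99 falls over 2-fold. When each array was centred on its median the split was 2452 higher and 3180 lower.

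The 3 lines were compared directly. The change differed between lines for 8892 genes, and between H1693 and H1993 alone for 3577. The 8 with the smallest p were led by the sulfotransferase SULT2B1, at -2.66, -0.14 and 2.17 in H1650, H1693 and H1993 (adjusted p = 9.76e-08), and FGFBP1, at 0.10, -2.76 and 0.64 (adjusted p = 3.64e-07). LGALS3BP was at -2.54, 1.81 and 1.41, and SLC39A1, SNHG29, RPS9, IFT52 and SLC1A5 had changes between -3.12 and -2.49 in H1650, the line with the 3' minus 5' difference, and between -0.23 and 0.89 in the other lines. Other probe sets of SLC39A1, SNHG29 and IFT52 in H1650 were at up to 0.29, -0.04 and 0.24. The changes of H1693 and H1993 correlated across genes (Pearson r = 0.389, Spearman 0.385), and those of H1650 had r = 0.141 with H1693 and r = 0.195 with H1993; genes are not independent replicates. H1693 and H1993 shared 1358 rises and 1124 falls, 2.60 and 3.00 times the numbers of independent lists. H1650 shared 1530 rises and 641 falls with H1693 (1.51 and 1.49 times) and 1737 rises and 672 falls with H1993 (1.54 and 1.71 times). Past the threshold with 1 sign in all 3 lines were 878 rises and 361 falls. Of the rises shared by H1693 and H1993, 195 were lower past the threshold in H1650, and of the shared falls 318 were higher there. The ATF4 list, with 4 higher and 8 lower in H1993 (adjusted p = 0.0731), differed between H1993 and H1693 (camera adjusted p = 6.87e-14; adjusted p = 0.0756 with an estimated correlation), and so did mitosis (adjusted p = 2.29e-07; adjusted p = 0.276 with an estimated correlation).

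Several lists near the subject of the series did not pass. Cisplatin transport and detoxification genes did not pass in any comparison (adjusted p = 0.436 over the 3 lines), although the copper exporter ATP7A rose by 0.92 and the efflux pump ABCC2 by 0.78 over the 3 lines, with probe sets of ATP7A as low as -0.12 in H1650 and of ABCC2 as low as -0.18 in H1693. The PAR polarity complex and its partners did not pass (adjusted p = 0.956 over the 3 lines), with PARD6B at 0.76, PATJ at 0.73 and PARD6A at -0.68. PARD6A was at -1.42 in H1650 and did not pass in H1693 or H1993 (-0.25 and -0.39), PARD6B was at 0.08 in H1693, and a probe set of PATJ was at -0.53 in H1650. Target genes of p53 had 13 of 27 higher and 7 lower over the 3 lines and did not pass (adjusted p = 0.316); in H1993 they passed in the fit without H1650 arrays (adjusted p = 0.0482, against 0.058 with them). Markers of fibroblasts, endothelium and leukocytes, cells that a pure culture should lack, did not pass in any line (camera adjusted p = 0.497 over the 3 lines, with 6 of 23 higher and 0 lower). A comparison of knockdown with control cannot show whether such cells were present in both. Lists for NRF2, hypoxia and glycolysis, mesenchymal genes, Hippo-YAP, Wnt, neuroendocrine and alveolar markers passed in none of the 4 comparisons either. In all, 23 of 38 lists passed in at least 1 comparison, 14 over the 3 lines, 9 in H1650, 18 in H1693 and 13 in H1993.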

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

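The tests of MARK2 in H1650, of RNA integrity for the cell cycle and interferon genes of H1693 and H1993, and of an unrelated hairpin were chosen only after the results were seen, as were the fits with the 3' minus 5' covariate and without H1650. The change after knockdown differed between the 3 lines for 8892 of 16205 genes, and for MARK2 itself (adjusted p = 0.000182). In the H1650 knockdown arrays, control probe sets that enter no comparison of genes had a mean 3' minus 5' difference of 6.82 for GAPDH and 7.06 for ACTB (log2). Among 100 splits drawn from those possible within lines, 1, the real one, gave as many as 7885 genes. The highest other count, 7093, came from a split that kept each line's groups whole and turned the sign of a line. The highest among splits that mixed the groups was 3799. Mixing the groups moves any difference between them into the residual spread. RNA integrity in H1650 or the order of the array codes could therefore also rank the real split first. The counts do not tell these from an effect of the knockdown.

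The large changes in H1650 went with RNA integrity. The difference between the H1650 control arrays was centred on its median over genes. Of the 765 genes that fell over 2-fold, a share of 0.825 was also lower in the control array with the larger 3' minus 5' difference. Of the 538 that rose over 2-fold, a share of 0.868 was higher there. Among 5897 genes that did not pass and also changed little, a share of 0.612 was lower in that array. RNA degradation may therefore account for much of these changes. Across genes the match was partial: the H1650 changes correlated at 0.33 with the difference of its control arrays, against 0.01 for H1693 and 0.01 for H1993. The 15 genes that rose and the 2 that fell over 2-fold in each line moved that far in H1693 and H1993 as well, where the arrays lack this difference. An effect of MARK2 knockdown stays open, since MARK2 changed by -0.29 in this line with a 95% interval from -0.65 to 0.07. Its signal in the H1650 control arrays, 5.94, was also near the floor of 5, where changes are understated. The knockdown arrays are those with the larger difference, so the design does not separate these explanations.

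Cell cycle genes were lower in H1693 and H1993. RNA degradation is argued against, since the GAPDH 3' minus 5' difference of knockdown and control arrays differed by -0.0324 in H1693 and 0.016 in H1993. Within codes 1 to 6 and within codes 7 to 12 the median change of the mitosis genes lay between -1.02 and -0.47 in these lines. Each of these sets of codes holds 1 array of every group, so a batch between the sets could not give this pattern by design. All control arrays have odd codes and all knockdown arrays even codes. An effect of code order can therefore not be told apart from treatment and stays open. An effect of the hairpin on other transcripts could give the same pattern and stays open, as does an effect of MARK2, because each line has 1 knockdown group and an empty vector as its control.

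Interferon-stimulated genes were higher in all 3 lines. For H1693 and H1993 RNA degradation is argued against by the same differences of -0.0324 and 0.016. Medians ran from 0.23 to 1.10 over both sets of codes and the lines. Each set holds every group, so these medians do not test a batch between the sets. Odd and even codes follow treatment here too, so an effect of code order stays open. In H1650 the 32 genes that rose had a median rise of 1.25. Scaled by the ratio of the 3' minus 5' differences, their median change between the control arrays was 0.33. Its 95% interval over resampled genes, 0.09 to 0.55, treats genes as independent and leaves out the spread between arrays. Part of the rise may therefore come from RNA integrity, and the test does not settle it. A response to a hairpin RNA as such cannot be told apart from an effect of MARK2, since 0 control groups carried an unrelated hairpin.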

How the results depend on the processing

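The covariate fit, the mean over H1693 and H1993, the fit without H1650 arrays and the crossed block were chosen after seeing the data. The cause was not tested for any difference below unless the setting itself shows it. With the title numbers as a replicate block within each line, 7617 genes passed over the 3 lines, 8398 in H1650, 4845 in H1693 and 4834 in H1993, and the numbers need not pair cultures: deviations of same-numbered arrays correlated at -0.105, -0.176 and 0.286 in the 3 lines. Crossed numbers gave 8235 over the 3 lines. List calls near the threshold were lost under blocks: the replicate block left 14, 9, 16 and 12 over the 3 lines and in H1650, H1693 and H1993, without cholesterol synthesis (0.0556) and MAPK genes (0.0514) in H1693 and apoptosis regulators (0.0517) in H1993. Array codes as a block left 11, 9, 18 and 13, without DNA damage signalling, fatty acid and TGF-beta genes over the 3 lines (adjusted p = 0.0513 each) and cholesterol synthesis in H1693 (0.0589), and with Hippo-YAP target genes (0.0397) there. As one shift over all lines the codes lost cholesterol synthesis in H1693 (0.0503).

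With all probe sets tested separately, which tests more features, 18520 passed over the 3 lines, 19957 in H1650, 11329 in H1693, 11182 in H1993, and 20366 differed between lines. A minimum of 1.5-fold left 1246, 3826, 1698 and 1857 in the same order, and the additive model, which counts line differences as spread, 3660 over the 3 lines. Camera with an estimated correlation passed 0 lists over the 3 lines, 0 in H1650, 2 in H1693 and 0 in H1993, with 7, 4, 12 and 9 at an unadjusted p below 0.05. Fry, which does not compare a list with other genes, passed 33, 32, 33 and 32. The correlation of H1693 with H1993 was 0.412 with the stricter filter, 0.371 with the mean of a gene's probe sets and 0.438 for brighter genes; with each array left out it ran from 0.375 (without H1693 knockdown replicate 1) to 0.390. MARK2 in H1650 passed after quantile normalisation (-0.44) and ran from -0.56 (without H1650 knockdown replicate 1) to -0.0189 (without replicate 2). A left-out array leaves a group with 1 array, assumed to vary like the others.

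With the GAPDH 3' minus 5' difference as a covariate, which nearly follows treatment in H1650, 30 genes passed over the 3 lines, 0 in H1650 (1233 at an unadjusted p below 0.05), and 2758 differed between lines; 5 lists passed in H1650. MARK2 over the 3 lines was -0.94 (SE 0.40, against 0.09 without the covariate) and no longer passed, and the correlations of H1650 with H1693 and H1993 were 0.0536 and 0.112. Signs turned over the 3 lines for DGAT1 (0.19), ELOVL1 (0.0837) and FASN (0.0802), and in H1650 for CDC45 (1.07), CLDN4 (0.17), PES1 (0.32), PMS1 (-0.93) and UBE2S (0.16). In the mean over H1693 and H1993 the signs of DGAT1 (0.31), ELOVL1 (0.18), RPL3 (0.0159) and SREBF1 (0.11) turned. Named genes other than MARK2, which is given above, had 7620 values under all alternatives. Of these, 7461 kept their side of the threshold with no counted turn of sign. A turn of sign was counted only where the main or the alternative fit passed, and by that rule 12 values turned. Another 145 no longer passed, 105 of them under the covariate, and 2 newly passed. The 2 were MARK3 in H1993 at -0.20 with centred arrays and MARK1 in H1650 at 0.37 without control replicate 2. Signal near background limits dim genes.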

Other observations

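The comparison of H1993 with the empty vector also moved genes of squamous differentiation. Of 19 measured squamous and basal cell markers, 8 rose and 2 fell in H1993 (median 0.29, camera adjusted p = 0.028; adjusted p = 0.187 with an estimated correlation), the same counts as adjusted over the list alone. The fit without H1650 arrays, chosen after seeing the data, lost this call (adjusted p = 0.0543). The cornified envelope genes IVL, SPRR1B and SPRR1A rose by 2.12, 1.85 and 1.76, and S100A9, a calcium-binding protein, by 1.42. In H1693 none rose and 2 fell, and the change of the list differed between H1993 and H1693 (camera adjusted p = 0.00224; adjusted p = 0.0802 with an estimated correlation).

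On the probe set used, 15 genes were over 2-fold higher in each line. They include LAMP3 at 2.30, 2.50 and 1.56 in H1650, H1693 and H1993, although its other probe set was at 0.47 in H1993. All 4 probe sets of KLRC3 were over 2-fold in each line, whereas most of the 15 had another probe set below 2-fold in some line.

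In H1993 LINC00473 fell by 2.55, and the nuclear receptor genes NR4A1 and NR4A2 fell by 1.43 and 1.00. The other probe set of LINC00473 was at -0.59, and those of NR4A1 ran from -2.00 to 0.07. All can be induced through the transcription factor CREB, so lower CREB-dependent transcription is a candidate explanation. Of 11 other CREB target genes listed before this test, 9 were measured, and their median change was 0.0176. Of these, 2 fell, NR4A3 (-0.94) and PDE4D (-0.66), and 2 rose, CREM (0.58) and PER1 (0.39). The 95% interval of the median over resampled genes, -0.66 to 0.11, leaves out the spread between arrays, and the test does not settle that explanation.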
